A study of Homo sapiens with 9 samples.

How the data were processed

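Total RNA of Daudi cells was amplified and labelled with biotin by in vitro transcription from the 3' end and hybridised to a short-oligonucleotide array, per the labels' protocols. Groups and replicate numbers were taken from the sample titles: 3 arrays each of Ctrl-sh, Slc7a5-sh and C-Myc-sh, 9 in all. The values deposited by the authors are log2 signals, 1 per probe set and array, in a table of the whole series. The submitters' processing notes name MAS5 as the tool, without a version. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal. The log2 base was read from the values: after raising them to linear scale, the mean with the lowest and highest 2% trimmed was 497 on each array, so each array had been scaled to one target. A scaled signal is relative, so a change in the total RNA per cell cannot be read from it. No further normalization was applied in the main analysis. MAS5 signals near background vary strongly on a log scale. The table held 0 missing values and 0 probe sets starting with AFFX, so the planned check of RNA quality from control probe sets was not run.

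The platform annotation gave 41091 of 54613 probe sets exactly 1 gene symbol, 1801 several and 11721 none. Of the 41091, 41037 were matched by Entrez ID to a RefSeq gene table, which changed 0 symbols; the older synonym of 1 list member was resolved the same way. Probe sets with several symbols or none were not used for genes. Of the probe sets of a gene the one with the highest mean over the 9 arrays was kept, which left 19775 genes. Genes were tested where that mean was at or above the median of all probe-set means (5.77 on the log2 scale, 54.6 linear), which left 11250 genes. Probe sets ending in _s_at or _x_at can also bind related transcripts. Coordinates are not reported here.

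The tests used R 4.3.3 and limma 3.58.1. One lmFit with 3 group means over all 9 arrays was followed by eBayes with a trend (6 residual and 8.21 prior degrees of freedom), with 3 contrasts, two-sided tests and Benjamini-Hochberg adjustment over the genes of a contrast. A gene was called at an adjusted p under 0.05. In a simulation of 11250 genes with the spread of these arrays, log2 changes of 0.5, 1 and 2 in size were put into 67, 67 and 66 genes. For Slc7a5-sh against Ctrl-sh, 43.3%, 79.1% and 93.9% of these were recovered, with 10 false calls among unchanged genes. For C-Myc-sh against Ctrl-sh the shares were 43.3%, 70.1% and 87.9%, with 8 false calls. A further list of genes was shifted by 0.5 and left out of these counts. A much larger share of genes was called in the real comparisons, and the cut-off of the adjustment depends on that share. The simulated recovery and false calls are therefore not those of the real tests.

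Gene lists were written from general knowledge, without use of these samples: 33 lists, of which the 30 with at least 8 tested members were tested. They covered MYC-induced and MYC-repressed genes, the MYC-MAX network, ribosome biogenesis, RNA polymerase I and III, cytosolic and mitochondrial ribosomal proteins, translation, amino acid transporters, the amino acid response, aminoacyl-tRNA synthetases, serine, nucleotide, polyamine, glutamine and proline, and branched-chain amino acid metabolism, glycolysis, oxidative phosphorylation, cholesterol synthesis, lysosome and autophagy, DNA replication, mitosis, p53 targets, the BCL2 family, the unfolded protein response, interferon-stimulated and NF-kB target genes, MHC class II, B-cell and plasma cell genes, and markers of T and NK, myeloid, and epithelial and fibroblast cells. Of the 44 amino acid response genes, 23 are also in another list, mainly those of transporters, synthetases and serine metabolism. SLC7A5 and MYC are in no list. Only 52 of 78 cytosolic ribosomal protein genes had a usable probe set. Shifts were tested with camera with a preset inter-gene correlation of 0.01, which compares a list with the other tested genes, adjusted over the lists of a contrast. camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it; fry gave 18, 26 and 27 lists for Slc7a5-sh, C-Myc-sh and their direct comparison. Marker lists were summarised over all measured members in a fit without the filter.

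The genes named in the text follow a rule: SLC7A5 and MYC; the 8 highest and 8 lowest called changes of each knockdown (5 and 5 in the direct comparison) among genes whose arrays do not overlap; and the 4 members with the smallest p in the direction of the shift of each shifted list, or the 2 with the smallest p of other lists, of which some are printed. Genes outside the rule are said to have been chosen after their values were seen.

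Overlap between the 2 knockdowns was set against 100 simulated experiments without effect that shared the controls, and against independent lists. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined. The alternatives were quantile normalization, centring on the array median, a pseudocount of 16, no filter or a 75th percentile filter, the mean of all probe sets, leaving out _s_at and _x_at probe sets, eBayes without trend, array weights, only the 6 arrays compared, the replicate number as a block, leaving out each array, a log2 change of at least 1, and probe sets instead of genes. Raising values below the filter level to it, and lists for heat shock and hypoxia, were added afterwards. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.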

Results

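Gene expression was measured in Daudi cells, a B-cell line established from a Burkitt lymphoma, a tumour in which MYC is placed under immunoglobulin gene control. The cells carried a control short hairpin RNA (Ctrl-sh), a hairpin against SLC7A5 (Slc7a5-sh) or a hairpin against MYC (C-Myc-sh), and were kept under puromycin for 48 h. SLC7A5 is the light chain of a membrane transporter of large neutral amino acids, among them leucine, and MYC is a transcription factor. Each of the 3 groups had 3 arrays, 9 in all, labelled as biological replicates. The labels do not say whether the replicates came from separate infections, so the p-values below measure the spread between these samples. The C-Myc-sh cells served as the study's positive control.

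Each array gave a signal for 54613 probe sets. The array medians lay between 6.05 and 6.26 on the log2 scale, and 11250 genes entered the tests. Pairs of arrays of one group correlated at 0.972 to 0.977 across the 11250 tested genes, which are not independent replicates. The first principal component held 53.8% of the variance and set the C-Myc-sh arrays apart from the other 2 groups, and the second held 12.2% and set Slc7a5-sh apart from Ctrl-sh. The number of arrays limits the precision of every value.

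The targeted genes were examined first. SLC7A5 had a log2 signal of 12.21 ± 0.15 (SD, n = 3) in Ctrl-sh, 11.89 ± 0.06 in Slc7a5-sh and 11.80 ± 0.03 in C-Myc-sh. In Slc7a5-sh it was lower by 20.0%, a log2 change of -0.32 (SE 0.07; 95% confidence interval -0.47 to -0.17; limma adjusted p = 0.00414), and all 3 arrays lay below the 3 control arrays. In C-Myc-sh the SLC7A5 change was -0.41 (SE 0.07, limma adjusted p = 0.000186). MYC fell to 46.9% of its control signal in C-Myc-sh, from 13.22 ± 0.05 to 12.13 ± 0.01 (SD, n = 3; log2 change -1.09, SE 0.05, limma adjusted p = 4.7e-10). MYC was also lower in Slc7a5-sh, at 12.87 ± 0.07, a fall of 21.3% (log2 change -0.35, SE 0.05, limma adjusted p = 0.000381). SLC7A5 was read by 1 probe set, and its level did not differ detectably between the 2 knockdowns (log2 difference -0.08, SE 0.07, limma adjusted p = 0.351).

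**Figure D1:**
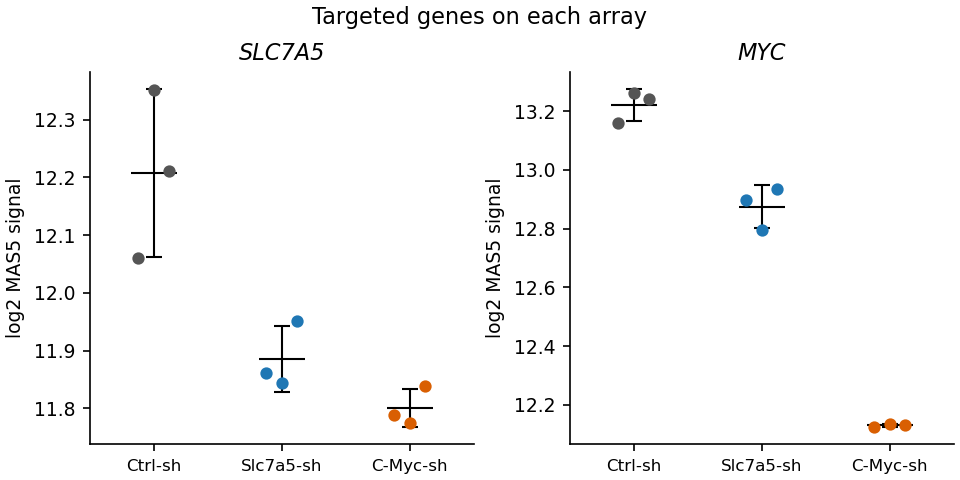
Log2 MAS5 signal of SLC7A5 (left) and MYC (right) on each of the 9 arrays, with points for single arrays, a horizontal line for the group mean and bars for 1 SD (n = 3). SLC7A5 averaged 12.21 in Ctrl-sh, 11.89 in Slc7a5-sh and 11.80 in C-Myc-sh, and MYC averaged 13.22, 12.87 and 12.13; the vertical axes do not start at 0.

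The comparison of Slc7a5-sh with Ctrl-sh asked how the cells' transcripts changed with the hairpin against SLC7A5. The SLC7A5 signal did not differ detectably between the knockdowns, and MYC was lower in both. The changes below can therefore not be tied to the SLC7A5 level alone, or told from other effects of the hairpin. Genes of the amino acid response, which the transcription factor ATF4 activates when amino acids are short, rose together. Glycolysis genes, genes of DNA replication, B-cell and germinal centre genes and MHC class II genes fell. Interferon-stimulated genes rose by a median log2 change of 0.46. HSPA6, an inducible HSP70-family chaperone, had the highest change of any called gene whose arrays did not overlap, from a log2 signal of 5.98 ± 0.18 to 9.96 ± 0.27 (SD, n = 3; 15.8-fold, SE 0.20 on the log2 scale, limma adjusted p = 4.0e-08).

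Of the 38 tested members of the amino acid response list, 25 rose and 0 fell (28 and 1 adjusted over the list alone), with a median log2 change of 0.40 (camera adjusted p = 2.4e-11). SLC7A11, which imports cystine, rose 3.86-fold (log2 change 1.95, SE 0.11, limma adjusted p = 9.2e-08). SLC38A2, a transporter of small neutral amino acids, rose by 0.69 on the log2 scale, PSAT1 of serine synthesis by 0.59 and asparagine synthetase ASNS by 0.62 (SE 0.05 to 0.06). Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and of which several are ATF4 targets, had 9 of 19 members up and 2 down (9 and 2 adjusted over the list alone, median 0.18, camera adjusted p = 0.00137). That call was lost with an estimated correlation (adjusted p = 0.376) and with the mean of all probe sets of a gene. TARS1 rose by 0.59 and WARS1 by 0.67.

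Glycolysis had 14 of 21 members lower and 0 higher (16 and 0 adjusted over the list alone, median -0.35, camera adjusted p = 2.9e-09). PDK1, which restrains entry of pyruvate into mitochondria, fell to a log2 signal of 11.07 ± 0.03 from 12.09 ± 0.05 (SD, n = 3; log2 change -1.02, SE 0.06, limma adjusted p = 1.3e-07). HK2, the hexokinase of the first glycolytic step, changed by -0.97 (SE 0.07, limma adjusted p = 9.6e-07), ALDOC by -1.12 and PGK1 by -0.42. DNA replication genes were lower in 23 of 40 members and higher in 1 (24 and 2 adjusted over the list alone, median -0.27, camera adjusted p = 4.2e-09), among them UHRF1 (-0.60), RFC3 (-0.55), GINS1 (-0.55) and E2F2 (-0.65). Nucleotide synthesis had 10 of 31 members lower and 1 higher (11 and 2 adjusted over the list alone, median -0.14, camera adjusted p = 0.0012; adjusted p = 0.125 with an estimated correlation). The ribonucleotide reductase subunits RRM2 (-0.41) and RRM2B (-0.67) were among those that fell.

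Genes of B-cell identity and of the germinal centre, the stage from which Burkitt lymphoma derives, were lower in 19 of 35 members and higher in 4 (21 and 4 adjusted over the list alone, median -0.26, camera adjusted p = 1.4e-06). VPREB3 changed by -1.24 (SE 0.13, limma adjusted p = 2.0e-05), the complement receptor CR2 by -0.89 and CD38 by -0.55. Of 17 MHC class II genes, which present peptide antigens, 9 fell and 2 rose (9 and 2 adjusted over the list alone, median -0.38, camera adjusted p = 8.0e-05). HLA-DRA fell from 13.39 ± 0.02 to 12.42 ± 0.05 (SD, n = 3; log2 change -0.97, SE 0.06, limma adjusted p = 1.1e-07), CD74 by -0.66 and HLA-DPB1 by -0.72.

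Interferon-stimulated genes, which carry out antiviral defence, were higher in 17 of 36 members and lower in 0 (18 and 0 adjusted over the list alone; camera adjusted p = 3.2e-05). IFIT2 changed by 1.20, SAMD9L by 0.95, IFIT3 by 0.88 and BST2 by 0.64. NF-kB target genes had 8 of 22 members up and 1 down (9 and 1 adjusted over the list alone, median 0.45, camera adjusted p = 0.00144; adjusted p = 0.0802 with an estimated correlation), with the inhibitor NFKBIA at 0.97 and the chemokine CCL4 at 0.91. Over the same arrays, markers of T and NK cells had a median log2 change of -0.75 over 22 measured genes, myeloid markers -0.37 over 18 and epithelial and fibroblast markers 0.12 over 24. Of these markers 0, 0 and 1 were called higher, the last being ACTA2, named after its values were seen, which lost its call with eBayes without trend.

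Genes of the BCL2 family and caspases, which set the threshold for apoptosis, were higher in 9 of 23 members and lower in 1 (10 and 1 adjusted over the list alone, median 0.32, camera adjusted p = 0.000449; adjusted p = 0.109 with an estimated correlation). PMAIP1, the pro-apoptotic NOXA, changed by 0.64 and CASP8 by 0.78. Of 16 genes listed as repressed by MYC, 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.19, camera adjusted p = 0.00593). This call was lost with an estimated correlation (adjusted p = 0.232) and without the _s_at and _x_at probe sets, and the median was 0.41 with the 75th percentile filter. TSC22D3, a glucocorticoid-induced gene, changed by 1.47 and the cell cycle inhibitor CDKN1B by 0.97. Genes listed as induced by MYC had 8 of 49 members up and 10 down (8 and 10 adjusted over the list alone) and did not pass (camera adjusted p = 0.395; median -0.04, mean 0.0011, so that their signs differed). Ribosome biogenesis, with 6 of 57 members up and 4 down (6 and 3 adjusted over the list alone; camera adjusted p = 0.965), and mitosis, with 8 of 40 up and 7 down (9 and 8 adjusted over the list alone; camera adjusted p = 0.508), did not pass camera either, while mitosis passed with fry (adjusted p = 0.0159).

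The remaining shifted lists had small medians. Cytosolic ribosomal proteins had 3 of 52 tested members up and 0 down (0 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 0.00323; adjusted p = 0.637 with an estimated correlation). RPL31, RPS15 and RPL24 changed by 0.20 to 0.23. The list no longer passed under quantile normalization, with fry or without Slc7a5-sh replicate 3 (median 0.07, camera adjusted p = 0.0803). The calls of RPL31, RPS15 and RPL24 were each lost without Ctrl-sh replicate 2 (0.21, 0.22 and 0.25), Ctrl-sh replicate 3 (0.15, 0.20 and 0.20), Slc7a5-sh replicate 1 (0.19, 0.23 and 0.20) or Slc7a5-sh replicate 3 (0.17, 0.14 and 0.15), and those of RPS15 and RPL24 without Ctrl-sh replicate 1 (0.22 and 0.23). RNA polymerase I and III genes had 7 of 30 up and 1 down (7 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.0363; adjusted p = 0.376 with an estimated correlation), with RRN3 at 0.43 and BRF2 at 0.55. This call was lost in 8 settings, among them without Ctrl-sh replicate 3 (median 0.20, camera adjusted p = 0.0746) and without Slc7a5-sh replicate 3 (median 0.10, camera adjusted p = 0.137). Oxidative phosphorylation had 15 of 66 members down and 4 up (15 and 6 adjusted over the list alone, median -0.04, camera adjusted p = 0.0339; adjusted p = 0.633 with an estimated correlation), with NDUFS7 at -0.54 and ATP5MC1 at -0.50. Its call was lost in 9 settings, among them without Ctrl-sh replicate 1 (median -0.02, camera adjusted p = 0.0995), without Ctrl-sh replicate 2 (median -0.04, camera adjusted p = 0.0577) and without Slc7a5-sh replicate 2 (median -0.0032, camera adjusted p = 0.298).

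In all, 2843 of 11250 genes differed between Slc7a5-sh and Ctrl-sh (limma, Benjamini-Hochberg adjusted), 1605 higher and 1238 lower, and 167 of them by 1 or more on the log2 scale. Of 30 lists tested, 14 were shifted, 8 up and 6 down, and 6 of these held with an estimated correlation. The other 16 lists had medians between -0.19 and 0.14 and camera adjusted p-values of 0.212 or more. DEPP1, a forkhead-factor target, rose from 5.24, below the filter level of 5.77, to 8.93 on the log2 scale, and against that level its change was 2.86. The next highest genes were USP18, MUC20, SLC6A13, RAG1, FCGBP and GIMAP2 (log2 changes 2.99 to 2.56), all below the filter level in Ctrl-sh. Against that level their changes were 0.29, 0.89, 0.81, 1.96, 1.09 and 1.76. SLC6A13 and FCGBP lost their call with eBayes without trend, and USP18 and SLC6A13 with only the 6 arrays compared. Without Ctrl-sh replicate 2 FCGBP changed by 1.62. The lowest of the genes named by the rule with a signal well measured in both groups was ABCG1, a sterol exporter (9.50 ± 0.10 to 7.53 ± 0.28, SD, n = 3; limma adjusted p = 1.6e-05). RIPOR3-AS1, GPT, C16orf86, FRMD5, C1RL, C4BPA and QPCTL (log2 changes -2.55 to -1.78) fell from log2 signals between 6.59 and 7.16 to below the filter level. All 7 lost their call without Ctrl-sh replicate 1 (-2.44 to -1.74) and without Ctrl-sh replicate 2 (-2.68 to -1.68). All but GPT lost it without Ctrl-sh replicate 3 (-2.54 to -1.72), and each lost it without 1 or more of the Slc7a5-sh arrays (-2.56 to -1.18). With values below that level raised to it, the changes of RIPOR3-AS1, C16orf86, FRMD5, C4BPA and QPCTL were -0.94, -1.28, -0.82, -1.10 and -0.99, and GPT (-0.84, limma adjusted p = 0.0559), C1RL (-0.76, limma adjusted p = 0.139) and USP18 (0.29, limma adjusted p = 0.44) no longer passed.

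Some members went against their list, a choice made after their values were seen. In Slc7a5-sh these were MXI1 of the MYC-repressed genes, POLR3C, FARSA, VARS1, APAF1 and REL, which fell. CTPS2, ATP5MC2, NDUFB3, NDUFS4, SDHC, UNG, CTSS, RFX5, CD79B, CXCR4, LMO2 and MEF2C rose. Of these, POLR3C, FARSA, VARS1, APAF1, CTPS2, NDUFB3, SDHC, LMO2 and MEF2C lost their call on leaving out 1 or more single arrays, among them Ctrl-sh replicate 3 for FARSA (-0.28), VARS1 (-0.54), APAF1 (-0.43), NDUFB3 (0.27), SDHC (0.18) and MEF2C (0.18), Slc7a5-sh replicate 1 for POLR3C (-0.22) and LMO2 (1.73), and Slc7a5-sh replicate 3 for CTPS2 (0.32). With the mean of all probe sets of a gene, HK2 (-0.19), TARS1 (0.31), CASP8 (0.33), CR2 (-0.39) and CD74 (-0.27) had smaller changes that did not pass, ASNS (0.87) and NFKBIA (1.01) did not pass though their changes were no smaller, and RFC3 (0.58), NDUFS7 (0.22), SAMD9L (-0.0013) and RPL31 (-0.09) turned. There PDK1 was at -0.68 and PGK1 at -0.78, and FARSA (-0.23), VARS1 (-1.24), CTPS2 (0.28), ATP5MC2, NDUFB3 (0.32), NDUFS4, APAF1 (-0.26), CD79B (0.55) and MEF2C did not pass. Without the _s_at and _x_at probe sets ASNS (1.11), C1RL (-0.24), C4BPA (-1.86), FARSA (-0.12), SDHC (0.22) and CTSS (0.16) did not pass, ATP5MC2 (-0.37) and MEF2C (-0.12) turned, HLA-DPB1 was at -2.23 and the glycolysis list had a median of -0.97. CXCR4 lost its call with eBayes without trend. The number of called genes was 1581 with the mean of all probe sets of a gene.

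The comparison of C-Myc-sh with Ctrl-sh was the study's positive control. Genes listed as induced by MYC fell, as did the separate lists of ribosome biogenesis, nucleotide synthesis, DNA replication and mitosis. Interferon-stimulated genes and NF-kB target genes rose by median log2 changes of 3.14 and 3.04, and MHC class II, lysosomal and MYC-repressed genes rose as well. The amino acid response list did not pass camera, with 16 of 38 members up and 16 down.

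Of 49 tested genes listed as induced by MYC, 42 fell and 2 rose (43 and 2 adjusted over the list alone, median -0.80, camera adjusted p = 5.4e-13). Spermidine synthase SRM fell from 13.06 ± 0.02 to 11.04 ± 0.09 (SD, n = 3; log2 change -2.02, SE 0.06, limma adjusted p = 4.2e-12), HK2 by -1.94, MRTO4 of ribosome assembly by -1.73 and the replicative helicase subunit MCM4 by -1.15. Ribosome biogenesis had 44 of 57 members lower and 3 higher (45 and 4 adjusted over the list alone, median -0.57, camera adjusted p = 1.5e-10), with LYAR at -2.13 and RRP1B at -1.39. Nucleotide synthesis had 29 of 31 lower and 1 higher (29 and 1 adjusted over the list alone, median -0.90, camera adjusted p = 3.3e-13), with PRPS1 at -1.66 and NME1 at -1.43. In DNA replication 37 of 40 genes fell and 0 rose (38 and 0 adjusted over the list alone, median -0.86, camera adjusted p = 9.2e-16), among them UHRF1 (-1.69), RFC3 (-1.65) and GINS2 (-1.55). In mitosis 36 of 40 fell and 0 rose (37 and 0 adjusted over the list alone, median -0.53, camera adjusted p = 4.4e-12), with BIRC5 at -1.04 and the cyclin CCNB2 at -0.97.

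Metabolic lists fell too. Glycolysis had 17 of 21 members lower and 2 higher (17 and 2 adjusted over the list alone, median -0.58, camera adjusted p = 3.1e-06), with GPI at -1.36 and LDHA at 50.1% of its control signal. Glutamine and proline metabolism had 9 of 11 lower and 1 higher (9 and 1 adjusted over the list alone, median -0.96, camera adjusted p = 0.000873), with PYCR1 at -1.60 and GLUD1 at -1.29. Serine and one-carbon metabolism had 13 of 18 lower and 2 higher (13 and 2 adjusted over the list alone, median -0.57, camera adjusted p = 0.000504), with GCSH at -1.72 and AHCY at -1.15. In polyamine metabolism 6 of 11 genes fell and 2 rose (6 and 2 adjusted over the list alone, median -0.53, camera adjusted p = 0.00953; adjusted p = 0.0561 with an estimated correlation). The list's median was -0.82 with the mean of all probe sets of a gene and -0.25 without C-Myc-sh replicate 2. ODC1, its first enzyme, fell from 14.67 ± 0.15 to 12.80 ± 0.03 (SD, n = 3; log2 change -1.88, SE 0.07, limma adjusted p = 1.5e-11).

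Mitochondrial ribosomal proteins had 55 of 75 members lower and 1 higher (56 and 1 adjusted over the list alone, median -0.35, camera adjusted p = 2.6e-10; adjusted p = 0.0608 with an estimated correlation), with MRPL4 at -1.35 and MRPL12 at -1.22. Translation initiation and elongation had 24 of 38 lower and 2 higher (24 and 2 adjusted over the list alone, median -0.25, camera adjusted p = 6.9e-05), with EIF4EBP1 at -2.32 and EIF5A at -0.96. That call was lost with an estimated correlation (adjusted p = 0.189) and under quantile normalization. Aminoacyl-tRNA synthetases had 11 of 19 lower and 4 higher (11 and 5 adjusted over the list alone, median -0.24, camera adjusted p = 0.0202), with VARS1 at -1.66 and FARSB at -0.99. Their call was lost with an estimated correlation (adjusted p = 0.446), under quantile normalization and without the _s_at and _x_at probe sets, where the list's median turned to 0.04 and FARSB to 0.38. Cytosolic ribosomal proteins had 13 of 52 lower and 0 higher (8 and 0 adjusted over the list alone, median -0.10, camera adjusted p = 0.00308; adjusted p = 0.561 with an estimated correlation), with RPL12 at -0.51 and RPL14 at -0.43. This call was lost in 5 settings, among them quantile normalization and without C-Myc-sh replicate 1 (median -0.05, camera adjusted p = 0.0534), and the median was -0.22 with arrays centred on their median. Over the settings the median shrank to as little as -0.0062. RPL14 was at -0.23 under quantile normalization.

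Interferon-stimulated genes were higher in 33 of 36 members and lower in 1 (33 and 1 adjusted over the list alone; camera adjusted p = 3.3e-16). IFIT3 rose 36.5-fold, from 8.37 ± 0.26 to 13.56 ± 0.04 (SD, n = 3; log2 change 5.19, SE 0.12, limma adjusted p = 3.9e-13). ISG15, a ubiquitin-like modifier, rose by 4.65 on the log2 scale, the RNA sensor IFIH1 by 3.93 and SAMD9 by 2.68. NF-kB target genes had 20 of 22 members up and 1 down (20 and 1 adjusted over the list alone; camera adjusted p = 1.8e-11). The costimulatory receptor CD40 rose 9.75-fold (log2 change 3.29, SE 0.08, limma adjusted p = 5.3e-13), ICAM1 by 4.04, NFKBIA by 3.47 and CD83 by 3.30. MHC class II genes had 14 of 17 up and 1 down (14 and 1 adjusted over the list alone, median 0.86, camera adjusted p = 1.3e-05), with HLA-DQA1 at 2.69, HLA-DRB1 at 1.38 and HLA-DRA at 1.00. Over these arrays markers of T and NK cells had a median log2 change of -0.29 (22 genes), myeloid markers -0.28 (18) and epithelial and fibroblast markers -0.20 (24), with 0, 0 and 1 genes called higher, the last again ACTA2. Called lower were 4, 1 and 0, namely CD247, GZMA, IL7R and LCK of the T and NK markers and the myeloid FCGR1A.

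**Figure D2:**
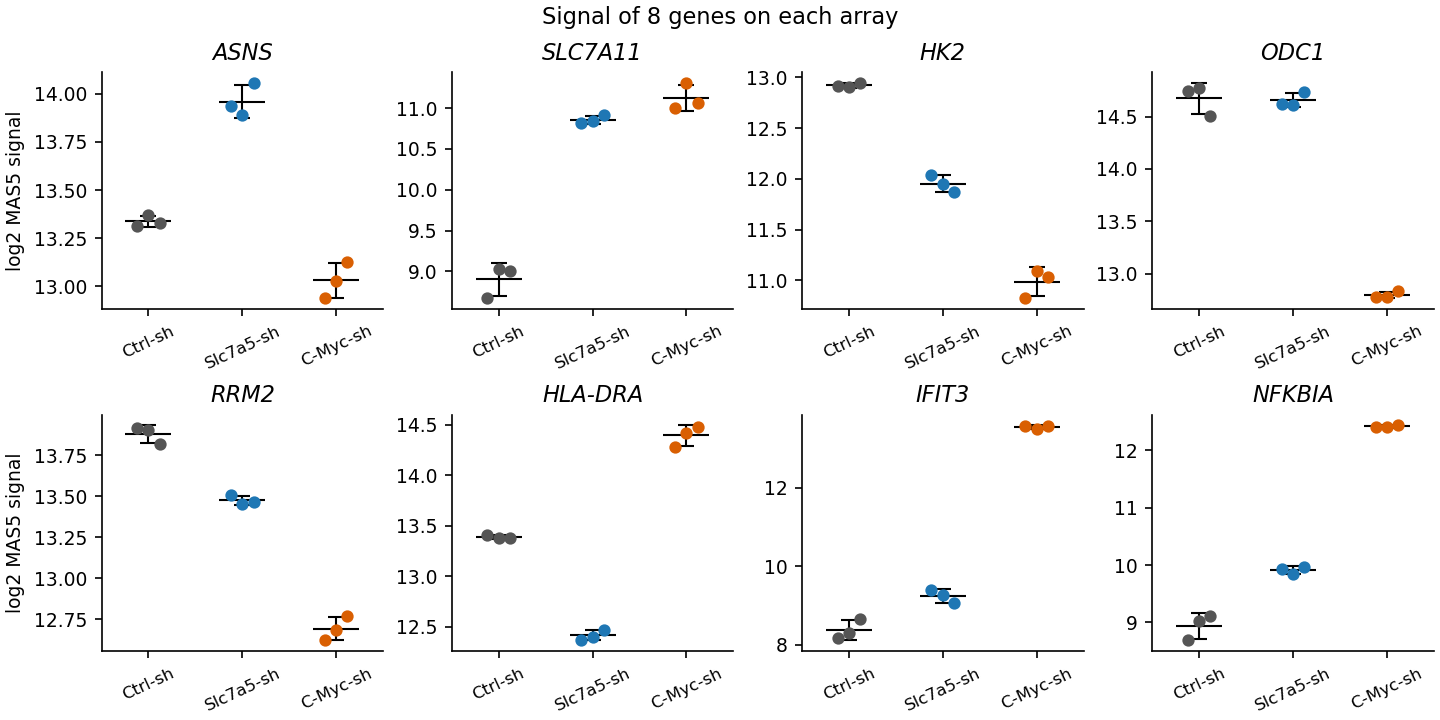
Log2 MAS5 signal of 8 genes on each of the 9 arrays, with points for single arrays, a horizontal line for the group mean and bars for 1 SD (n = 3); the vertical axes differ and do not start at 0. HLA-DRA averaged 13.39 in Ctrl-sh, 12.42 in Slc7a5-sh and 14.40 in C-Myc-sh, and IFIT3 averaged 8.37, 9.24 and 13.56.

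MYC-repressed genes were higher in 12 of 16 members and lower in 1 (12 and 1 adjusted over the list alone, median 1.11, camera adjusted p = 3.1e-05), with TSC22D3 at 2.95 and CDKN1B at 1.99. Lysosome and autophagy genes, many of them targets of the transcription factor TFEB, were higher in 27 of 40 and lower in 5 (29 and 5 adjusted over the list alone, median 0.62, camera adjusted p = 0.000156). The protease CTSS changed by 1.72, the autophagy receptor SQSTM1 by 1.53 and TFEB itself by 1.26. Without the _s_at and _x_at probe sets CTSS was at 0.63 and SQSTM1 at 0.75, and both passed. Cholesterol synthesis had 12 of 18 up and 3 down (12 and 3 adjusted over the list alone, median 0.66, camera adjusted p = 0.00137; adjusted p = 0.0725 with an estimated correlation), with MSMO1 at 1.93 and HMGCS1 at 1.87. BCL2 family and caspase genes had 11 of 23 up and 2 down (11 and 2 adjusted over the list alone, median 0.28, camera adjusted p = 0.0199), with XIAP at 1.07 and BIRC2 at 1.01, apoptosis inhibitors that the list also holds. This call was lost with an estimated correlation (adjusted p = 0.189) and without the _s_at and _x_at probe sets, and the median was 0.15 under quantile normalization. B-cell and germinal centre genes were lower in 22 of 35 and higher in 9 (22 and 9 adjusted over the list alone, median -0.30, camera adjusted p = 0.00311), with the transcriptional regulator ID3 at -1.85 and TCL1A at -1.72. Their median was -0.20 without the _s_at and _x_at probe sets. The amino acid response list (16 and 16 adjusted over the list alone; camera adjusted p = 0.514, fry adjusted p = 1.1e-05) had a median of -0.07 and a mean of 0.22, so that their signs differed. SLC7A11 (2.22) and SLC38A2 (1.24) were among its members that rose.

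In all, 6178 of 11250 genes differed between C-Myc-sh and Ctrl-sh (limma, Benjamini-Hochberg adjusted), 3234 higher and 2944 lower, and 1607 of them by 1 or more on the log2 scale. Of 30 lists tested, 21 were shifted, 7 up and 14 down, and 14 of these held with an estimated correlation. The other 9 lists had medians between -0.24 and 0.15. The highest changes were those of IFI44L, CCL22, EBI3, LINC00158, IFIT1, SLAMF1, IFI27 and BCL2A1 (log2 changes 10.33 to 6.11). IFI44L, CCL22, EBI3, LINC00158, IFIT1 and IFI27 lay below the filter level in Ctrl-sh, and against that level their changes were 7.42, 6.43, 6.01, 6.61, 6.39 and 3.73. SLAMF1, a B- and T-cell surface receptor, rose by 6.87 (SE 0.21, limma adjusted p = 4.2e-12) and the anti-apoptotic BCL2A1 by 6.11 (SE 0.21, limma adjusted p = 1.2e-11). The lowest were SLC33A2, TRIB1, PVRIG, TCL1B, CSMD1, IL7R, VWCE and KHK (log2 changes -3.73 to -3.19), of which SLC33A2, VWCE and KHK fell below the filter level. With values below that level raised to it, the changes of SLC33A2, IL7R, VWCE and KHK were -1.92, -3.20, -2.16 and -2.60. VWCE was at -2.10 without C-Myc-sh replicate 1, and CSMD1 at -2.26 with the mean of all probe sets of a gene. TRIB1 (-1.78) no longer passed with the mean of all probe sets of a gene, nor did RFC3 (-0.41) and CCNB2 (-0.48), and GINS2 (-0.55), MRPL12 (-0.66), MRPL4 (-0.20) and RPL14 (-0.51) no longer passed without the _s_at and _x_at probe sets.

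The split between higher and lower genes depended on the array scaling. With each array centred on its median over the tested genes, 2615 genes were higher and 3668 lower in C-Myc-sh, and the median log2 change of all genes moved from 0.04 to -0.07, so changes are relative to the scaling of the arrays. Some members again went against their list, a choice made after their values were seen. DUSP2, TBRG4, NGDN, NMD3, SDAD1, EIF1, EIF4G2, CARS1, TARS1, TARS3, WARS1, MAT2B, MTR, CTPS2, AZIN1, SAT1, GOT1, ALDOC, SLC2A3 and MRPS33 rose. MXI1, EBP, PMVK, TM7SF2, BNIP3, BNIP3L, DEPTOR, GLA, SESN1, BIK, HRK, ISG20, REL and RFXAP fell. The call of CTPS2 was lost without any 1 Ctrl-sh array (0.27 to 0.30) or C-Myc-sh replicate 2 (0.21), that of SAT1 without Ctrl-sh replicate 1 (0.16) or 3 (0.27) or C-Myc-sh replicate 2 (0.25) or 3 (0.25), and that of REL without C-Myc-sh replicate 3 (-0.19). With arrays centred on their median, NGDN, SDAD1, EIF4G2, MTR, CTPS2 and SAT1 did not pass. With the mean of all probe sets NGDN, SDAD1, EIF4G2, CARS1, CTPS2, EBP and REL did not pass, and TARS3 (-0.28) and MTR (-0.0033) turned.

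The changes in the 2 knockdowns were then set side by side. As lists, glycolysis, DNA replication and B-cell genes were lower in both, and interferon-stimulated genes were higher in both. The B-cell list was not uniform, since some of its members were called higher in each knockdown. With the preset correlation, nucleotide synthesis was also lower in both, and NF-kB target, MYC-repressed and BCL2 family genes were higher in both. These 4 calls were lost in Slc7a5-sh with an estimated correlation (adjusted p = 0.125, 0.0802, 0.232 and 0.109), as was that of the BCL2 family in C-Myc-sh (adjusted p = 0.189). The BCL2 family list holds genes that act for and against apoptosis, so its rise gives no shared direction of that process. Its named risers were PMAIP1 and CASP8 in Slc7a5-sh and the inhibitors XIAP and BIRC2 in C-Myc-sh, where the pro-apoptotic BIK and HRK fell. Without the _s_at and _x_at probe sets, MYC-repressed genes did not pass in Slc7a5-sh, nor the BCL2 family in C-Myc-sh. HK2 changed by -0.97 in Slc7a5-sh and by -1.94 in C-Myc-sh, and SLC7A11 by 1.95 and 2.22. Across genes, 1100 were called higher in both and 821 lower in both, 1921 in all, and 285 were called in opposite directions. Independent lists of these sizes would share 461 higher and 324 lower genes, 785 in all, with 776 in opposite directions, and simulated groups without effect against the same 3 controls shared 0. Those groups held no real changes, so this 0 does not measure what shared controls add to an overlap of real ones. Of the 1238 genes lower in Slc7a5-sh, 66.3% were also lower in C-Myc-sh, and of the 1605 higher genes, 68.5% were also higher.

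Across genes, which are not independent replicates, the log2 changes of the 2 knockdowns had a Pearson r of 0.507 and a Spearman rho of 0.503. Simulated groups without effect against the same controls gave 0.499 (range of 100 simulations 0.455 to 0.537) and 0.445 (0.418 to 0.469). Sharing the controls alone sets these simulated values, so they do not measure how much of the observed ones the controls add. The covariance was 0.182 against a simulated 0.0402, a difference of 0.142. This difference leaves out the covariance that the shared controls add. The 3 control arrays are too few to split with 2 in each part, so some of the excess of shared genes over independent lists may come from the shared controls. The number of genes changed the same way was 1092 with the mean of all probe sets of a gene.

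**Figure D3:**
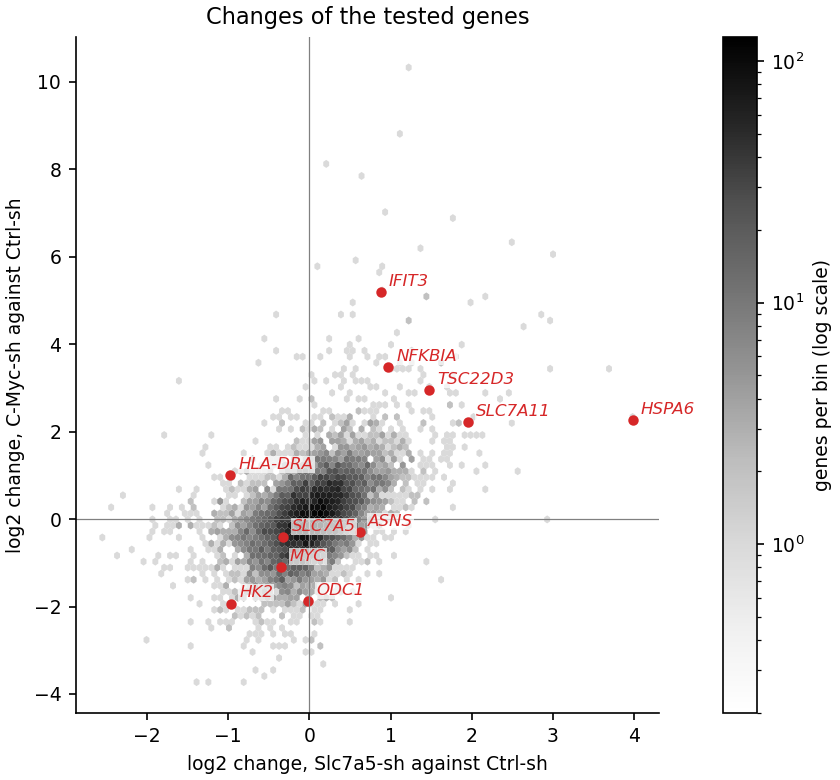
Log2 change of each of the 11250 tested genes in Slc7a5-sh (horizontal) and C-Myc-sh (vertical) against Ctrl-sh, with grey hexagons shaded by the number of genes on a log scale and red points for 11 named genes. Pearson r was 0.507 and Spearman rho 0.503 across genes, against 0.499 and 0.445 in simulated groups without effect that shared the controls. Those groups held no real changes, so their values do not measure how much of the observed ones the shared controls add.

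The 2 knockdowns were also compared directly. Relative to Slc7a5-sh, C-Myc-sh had higher interferon-stimulated, NF-kB target, MHC class II and lysosomal genes. It had lower MYC-induced, mitosis, ribosome biogenesis, DNA replication and nucleotide synthesis genes. MYC itself was lower in C-Myc-sh by a log2 difference of -0.74 (SE 0.05, limma adjusted p = 4.1e-08). HLA-DRA was higher in C-Myc-sh by 1.98 (SE 0.06, limma adjusted p = 4.4e-12) and HLA-DQA1 by 3.11.

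Of the 36 interferon-stimulated genes 33 were higher in C-Myc-sh than in Slc7a5-sh and 1 lower (33 and 1 adjusted over the list alone, median 2.82, camera adjusted p = 1.4e-17), with IFIT3 at 4.31 and IFIH1 at 3.39. NF-kB target genes were higher in 19 of 22 and lower in 0 (21 and 0 adjusted over the list alone, median 2.26, camera adjusted p = 8.4e-13), with CD40 at 3.26 and CD83 at 2.94. MHC class II genes were higher in 14 of 17 and lower in 1 (15 and 1 adjusted over the list alone, median 1.10, camera adjusted p = 8.3e-09). Lysosome and autophagy genes were higher in 27 of 40 and lower in 4 (27 and 4 adjusted over the list alone, median 0.54, camera adjusted p = 4.4e-06), with CTSS at 1.08 (0.47 without the _s_at and _x_at probe sets). MYC-repressed genes (10 of 16 higher, 0 lower; 10 and 0 adjusted over the list alone, median 0.85) and cholesterol synthesis (12 of 18 higher, 2 lower; 12 and 2 adjusted over the list alone, median 0.44, MSMO1 1.45) passed as well. These 2 calls were lost with an estimated correlation (adjusted p = 0.0619 and adjusted p = 0.0528).

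Mitosis genes were lower in 39 of 40 and higher in 1 (39 and 1 adjusted over the list alone, median -0.64, camera adjusted p = 7.3e-15), with BIRC5 at -1.28 and CCNB2 at -1.11. MYC-induced genes were lower in 45 of 49 and higher in 1 (45 and 1 adjusted over the list alone, median -0.83, camera adjusted p = 6.9e-15), with SRM at -1.86 and MRTO4 at -1.82. Ribosome biogenesis was lower in 45 of 57 and higher in 0 (47 and 0 adjusted over the list alone, median -0.67, camera adjusted p = 1.4e-13), with LYAR at -2.15 and NHP2 at -0.94. DNA replication was lower in 35 of 40 and higher in 1 (36 and 1 adjusted over the list alone, median -0.63, camera adjusted p = 9.7e-13), with GINS2 at -1.34. Nucleotide synthesis was lower in 25 of 31 and higher in 1 (26 and 1 adjusted over the list alone, median -0.80, camera adjusted p = 2.0e-12), with NME1 at -1.46. Glutamine and proline metabolism (8 of 11 lower, 1 higher; 8 and 1 adjusted over the list alone, median -0.70, camera adjusted p = 0.00171) lost its call without the _s_at and _x_at probe sets, and serine and one-carbon metabolism (12 of 18 lower, 3 higher; 13 and 3 adjusted over the list alone, median -0.48) had a camera adjusted p of 0.000272.

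Amino acid response genes were lower in C-Myc-sh in 21 of 38 and higher in 9 (21 and 10 adjusted over the list alone, median -0.29, camera adjusted p = 0.0257). The call was lost with an estimated correlation (adjusted p = 0.0801), under quantile normalization and with the 75th percentile filter. EIF4EBP1 differed by -2.38, PHGDH by -1.09, ASNS by -0.93 and PSAT1 by -0.75. Aminoacyl-tRNA synthetases were lower in 16 of 19 and higher in 1 (16 and 1 adjusted over the list alone, median -0.47, camera adjusted p = 4.4e-06; adjusted p = 0.132 with an estimated correlation), with EPRS1 at -0.69 and KARS1 at -0.55. The median was -0.26 without the _s_at and _x_at probe sets, EPRS1 was at -0.41 with the mean of all its probe sets, and KARS1 at -0.37 under quantile normalization. Cytosolic ribosomal proteins were lower in 38 of 52 and higher in 0 (39 and 0 adjusted over the list alone, median -0.23, camera adjusted p = 7.5e-07), with RPL12 at -0.49 and RPL36 at -0.41. Their call was lost with an estimated correlation (adjusted p = 0.368) and under quantile normalization, where RPL12 was at -0.29, and RPL36 turned to 0.43 with the mean of all its probe sets. Mitochondrial ribosomal proteins were lower in 50 of 75 and higher in 3 (54 and 3 adjusted over the list alone, median -0.34; adjusted p = 0.0715 with an estimated correlation). Translation genes were lower in 25 of 38 and higher in 1 (25 and 1 adjusted over the list alone, median -0.27, and -0.16 under quantile normalization; adjusted p = 0.13 with an estimated correlation). RNA polymerase I and III genes were lower in 15 of 30 and higher in 1 (15 and 1 adjusted over the list alone, median -0.23; adjusted p = 0.122 with an estimated correlation), with POLR3G at -1.98.

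Polyamine metabolism (6 of 11 lower, 1 higher; 6 and 1 adjusted over the list alone, median -0.25; adjusted p = 0.0619 with an estimated correlation) and glycolysis (12 of 21 lower, 3 higher; 12 and 3 adjusted over the list alone, median -0.23; adjusted p = 0.163 with an estimated correlation) were also lower in C-Myc-sh. The polyamine median was -0.43 without Slc7a5-sh replicate 1 and -0.44 with the 75th percentile filter. The glycolysis difference was lost as well under quantile normalization, with eBayes without trend and without the _s_at and _x_at probe sets, where its median turned to 0.02. In all, 5569 of 11250 genes differed (limma, Benjamini-Hochberg adjusted), 2743 higher and 2826 lower in C-Myc-sh, 1088 of them by 1 or more on the log2 scale. Of 30 lists, 21 were shifted, 6 up and 15 down, and 11 of these held with an estimated correlation. The highest differences were those of IFI44L, EBI3, CCL22, LINC00158 and IFIT1 (9.13 to 6.16), the first 4 from signals below the filter level in Slc7a5-sh, and against that level these 4 differed by 7.42, 6.01, 6.33 and 6.73. The lowest were those of VWCE, ASS1, GIRGL, CSMD1 and TERT (-3.51 to -3.02), with VWCE and TERT below the filter level in C-Myc-sh. With values below that level raised to it, the differences of VWCE, ASS1, GIRGL and TERT were -2.33, -2.91, -2.88 and -1.97. VWCE differed by -2.27 without C-Myc-sh replicate 1, and CSMD1 by -1.83 with the mean of all probe sets of a gene. DUSP2, ANLN and GINS3 were higher and ISG20 and RFXAP lower against their lists, named after their values were seen. ANLN lost its call without Ctrl-sh replicate 1 (0.19), Slc7a5-sh replicate 1 (0.15) or 3 (0.20), or C-Myc-sh replicate 1 (0.15) or 2 (0.18), and turned to -0.13 without the _s_at and _x_at probe sets. There ASNS (-1.36) and GINS2 (-0.31) no longer passed, and CCNB2 (-0.31) and GINS2 (-0.59) did not with the mean of all probe sets of a gene.

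**Figure D4:**
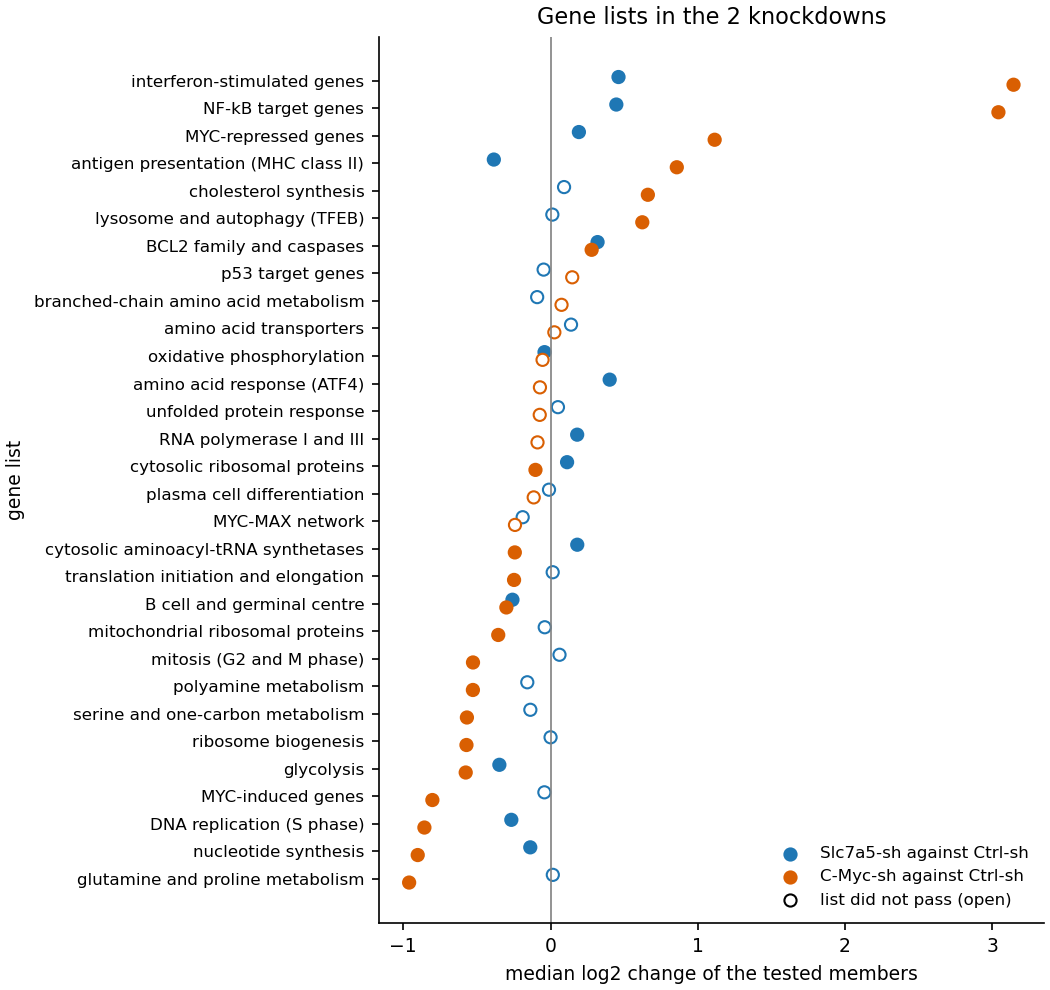
Median log2 change of the tested members of each of 30 gene lists in Slc7a5-sh (blue) and C-Myc-sh (orange) against Ctrl-sh; filled points passed camera and open points did not. The MHC class II list had medians of -0.38 and 0.86, the amino acid response list 0.40 and -0.07, and the interferon-stimulated genes 0.46 and 3.14.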

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

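The tests of hairpin sensing, of the SLC7A5 signal and with the heat shock list, and all counts over splits of the arrays, were chosen only after the results were seen.

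MHC class II genes, cytosolic ribosomal proteins and aminoacyl-tRNA synthetases stood out because the 2 knockdowns moved them in opposite directions and differed when tested directly. MHC class II genes had medians of -0.38 in Slc7a5-sh and 0.86 in C-Myc-sh, a median difference of 1.10 (camera adjusted p = 8.3e-09). Cytosolic ribosomal proteins had medians of 0.11 and -0.10, a median difference of -0.23 (camera adjusted p = 7.5e-07), and both single calls and the difference were lost with an estimated correlation (adjusted p = 0.637, 0.561 and 0.368). All of these calls were also lost under quantile normalization. Over the settings the medians shrank to as little as 0.022 and -0.0062, and the difference to -0.045. Aminoacyl-tRNA synthetases had medians of 0.18 and -0.24, a median difference of -0.47 (camera adjusted p = 4.4e-06), and here too both single calls and the difference were lost with an estimated correlation (adjusted p = 0.376, 0.446 and 0.132). Their opposite directions did not hold throughout: the C-Myc-sh median was 0.04 without the _s_at and _x_at probe sets, and the Slc7a5-sh median was 0.05, without passing, with the mean of all probe sets of a gene.

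Interferon-stimulated genes rose in C-Myc-sh by a median log2 change of 3.14, beside 3.04 for NF-kB target genes. Array scaling is argued against, since the median log2 change was 3.02 under quantile normalization and 3.02 with centring. Admixed T and NK, myeloid, and epithelial and fibroblast cells were looked for with 3 marker lists, whose highest median in C-Myc-sh was -0.20 (resampling SE 0.28). Of these markers 0, 0 and 1 were called higher and 4, 1 and 0 lower. The lists' median signals in Ctrl-sh were 4.97, 4.76 and 4.99, below the filter level. Signals near background vary strongly, so these medians show no rise but cannot exclude admixture. Another B-cell line was not tested. Sensing of the hairpin or virus stays open: the interferon-stimulated list rose by a median of 0.46 in Slc7a5-sh, and the labels give no second hairpin per gene. An effect of lower MYC on interferon and NF-kB signalling may contribute and stays untested by this design.

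SLC7A5 fell by only 20.0% in the cells carrying its hairpin. Its level did not differ detectably from that in C-Myc-sh, whose hairpin targets MYC (log2 difference -0.08, limma adjusted p = 0.351). Whether the SLC7A5 hairpin acted only weakly, or the fall followed the lower MYC, was not tested and stays open. Saturation of the array as a whole is argued against, since 132 of 1290 genes at or above its control signal were called lower by 1 or more on the log2 scale in C-Myc-sh. These are other probe sets, so saturation of the single SLC7A5 probe set stays open. Re-induction by the amino acid response stays open. Of 4 tested transporter genes of that response, 3 rose in the same cells: SLC38A2 (0.69), SLC7A1 (0.32) and SLC7A11 (1.95). SLC3A2 was at 0.22 (limma adjusted p = 0.0793) and passed without Slc7a5-sh replicate 3 (0.29). SLC7A1 did not pass with the mean of all its probe sets and turned to -0.12 without the _s_at and _x_at probe sets, which leaves 2 of the 4. These genes belong to the list already found higher, so their rise is no separate test. SLC7A11 (2.22) and SLC38A2 (1.24) also rose in C-Myc-sh, where that list did not pass camera. Signal from related transcripts stays open, because only 1 probe set names SLC7A5 alone.

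HSPA6 had the highest change in Slc7a5-sh over all 9 arrays, among called genes whose arrays did not overlap, but without Ctrl-sh replicate 3 DEPP1 changed by more (4.41). A probe-set artefact is argued against, since its second probe set rose by 3.29 (SE 0.30), and array scaling too, since the change was 3.97 under quantile normalization and 3.94 with centring. A general heat shock response stays open: the heat shock list had a median of 0.15 (camera adjusted p = 0.0507; adjusted p = 0.16 with an estimated correlation), with 5 of 14 genes up and 2 down. HSPA1A, HSPA1B and HSPB1 were not among the 14 tested genes, so the list's median does not cover them. HSPA6, looked up in C-Myc-sh after its values were seen, was also higher there (2.27, SE 0.20), so the rise may not be specific to the SLC7A5 hairpin.

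Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05, and 1 of the 10 splits, the real one, reached the real value each time. For genes the real values were 2843 (Slc7a5-sh against Ctrl-sh), 6178 (C-Myc-sh against Ctrl-sh) and 5569 (C-Myc-sh against Slc7a5-sh), and the highest other value was 0 in each. For lists they were 14, 21 and 21, and the highest other values were 11, 18 and 16. Every other split puts arrays of both groups on each side, so part of the real difference stays and also widens the spread. Neither the 0 for genes nor the values for lists is therefore a chance level.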

How the results depend on the processing

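Raising low values to the filter level and the lists for heat shock and hypoxia were chosen only after the data were seen. Counts of called genes and of shifted lists stayed within 1.5 times the main value in all settings but these: with the mean of all probe sets of a gene, 1581 genes in Slc7a5-sh and 1092 changed the same way in both knockdowns; with a log2 change of at least 1 as well, 167, 1607 and 1088 genes in Slc7a5-sh, C-Myc-sh and their direct comparison; with probe sets instead of genes, 5035, 12526 and 10868; and with an estimated correlation, 6 lists in Slc7a5-sh and 11 in the direct comparison. The stricter threshold and the larger number of probe sets tested account for their own counts; for the mean of all probe sets the cause was not tested. The changes of SLC7A5 and MYC kept their direction and their call in each setting that gave a value. Neither gene has a value without the _s_at and _x_at probe sets, and the shared results have none with only the 6 arrays compared.

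Leaving out each array gave 2246 to 2811 genes and 12 to 14 lists in Slc7a5-sh, 5695 to 6296 and 20 to 21 in C-Myc-sh, and 5005 to 5524 and 21 to 21 between them. SLC7A5 ranged from -0.40 to -0.25 in Slc7a5-sh and from -0.48 to -0.34 in C-Myc-sh, and MYC from -0.38 to -0.31 and from -1.12 to -1.07. Genes changed the same way numbered 1550 to 1837, and r was 0.472 to 0.539. With 1 array left out, its group of 2 shares the spread estimated over the other groups.

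With the replicate number as a block, 2775, 6147 and 5526 genes, 14, 21 and 21 lists and 1858 genes changed the same way were found. Residuals of arrays with the same number correlated at -0.02 to 0.02, and 2 of 9 arrays matched their own number best, so the numbers were not taken to pair the samples.

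Oxidative phosphorylation, not shifted in C-Myc-sh, passed upward under quantile normalization, with medians of 0.13 against Ctrl-sh and 0.15 against Slc7a5-sh, and downward against Ctrl-sh with arrays centred on their median (-0.17). Of the named genes, the following turned. With the mean of all probe sets these were NDUFS7 (0.22), RFC3 (0.58), SAMD9L (-0.0013), RPL31 (-0.0905) and HSPH1 (-0.0143) in Slc7a5-sh, TARS3 (-0.28) and MTR (-0.0033) in C-Myc-sh, and RPL36 (0.43) between the knockdowns. Without the _s_at and _x_at probe sets they were ATP5MC2 (-0.37), MEF2C (-0.12), SLC7A1 (-0.12) and HSPH1 (-0.28) in Slc7a5-sh, FARSB (0.38) in C-Myc-sh, and ANLN (-0.13) between them. Both settings read these genes through other probe sets. Over all settings, 229 values of named genes and 60 of single lists lost their call without camera or limma turning, 4786 and 1980 stayed on their side of the threshold, and 1 and 22 gained a call. The medians of lists turned in 2 values of shifted lists, both without the _s_at and _x_at probe sets (synthetases in C-Myc-sh, 0.04, and glycolysis between the knockdowns, 0.02), and in 72 values of other lists. Low signals limit the largest changes: raised to the filter level, values gave 2912, 6280 and 5638 called genes.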

Other observations

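The hypoxia and heat shock lists were written, and their tests chosen, only after the first results were seen, before their own values were. Their members are named after their values were seen.

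Plasma cell genes did not pass camera in C-Myc-sh (5 of 14 up, 7 down; 5 and 7 adjusted over the list alone, median -0.11, camera adjusted p = 0.282). They passed with the mean of all probe sets of a gene (median -0.24) and with fry (adjusted p = 1.0e-05). MZB1, a chaperone of antibody-secreting and marginal zone B cells, changed by -2.94 (SE 0.08, limma adjusted p = 1.3e-12) and FKBP11 by -1.06. In Slc7a5-sh MZB1 changed by -0.40 (SE 0.08, limma adjusted p = 0.00215). p53 target genes had 10 of 22 members up and 5 down in C-Myc-sh (11 and 6 adjusted over the list alone, median 0.15, camera adjusted p = 0.453), with the death receptor FAS at 3.76 (SE 0.14) and MDM2 at -0.79. FAS did not pass without the _s_at and _x_at probe sets (1.81). Branched-chain amino acid genes were mixed (8 of 20 up, 3 down; 8 and 3 adjusted over the list alone, median 0.07), with the transaminase BCAT1 at -1.05 and the dehydrogenase subunit DBT at 0.76, which did not pass with the mean of all probe sets of a gene. Amino acid transporters had 10 of 28 up and 13 down (10 and 13 adjusted over the list alone, median 0.03, mean -0.07), the unfolded protein response 8 of 25 up and 7 down (8 and 7 adjusted over the list alone, median -0.07, mean 0.07), and the MYC-MAX network 0 of 9 up and 3 down (0 and 3 adjusted over the list alone, median -0.24). RNA polymerase I and III genes did not pass camera in C-Myc-sh (6 of 30 up, 12 down; 6 and 12 adjusted over the list alone, median -0.09, camera adjusted p = 0.104), with POLR3G at -1.65 and GTF3A at -1.39 (-0.52 without the _s_at and _x_at probe sets). They passed with no filter and with fry (adjusted p = 0.000306). With fry the p53 target genes (adjusted p = 0.00338), the unfolded protein response (adjusted p = 0.00309) and the MYC-MAX network (adjusted p = 0.036) passed as well.

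In Slc7a5-sh, lists related to the transporter's substrates did not pass camera: amino acid transporters (4 of 28 up, 2 down; 4 and 2 adjusted over the list alone, median 0.14, camera adjusted p = 0.212), branched-chain amino acid metabolism (3 of 20 up, 6 down; 4 and 6 adjusted over the list alone, median -0.09) and polyamine metabolism (2 of 11 up, 3 down; 2 and 4 adjusted over the list alone, median -0.16). All 3 passed with fry, which does not compare a list with other genes (adjusted p = 0.000491, 0.00763 and 0.0156). Single genes changed: the mitochondrial transaminase GOT2 by -1.12 (SE 0.07, limma adjusted p = 3.3e-07) and AMD1 of polyamine synthesis by -0.57 (SE 0.08).

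The lower glycolysis genes of Slc7a5-sh may reflect lower activity of HIF1A, a hypothesis tested with a list of its targets. That list had a median of -0.35 (camera adjusted p = 2.4e-06; adjusted p = 0.0587 with an estimated correlation), with 11 of 23 genes lower and 0 higher. BNIP3 (-1.07) was among the lower genes. The other members were not called, VEGFA (0.07) and SLC2A1 (-0.11) among them. Without the glycolysis genes, 8 of 19 were lower and 0 higher (median -0.23). In C-Myc-sh the list had a median of -0.40 (camera adjusted p = 0.00911; adjusted p = 0.185 with an estimated correlation), so a lower MYC level could account for part of it. MYC-induced genes did not pass as a list in Slc7a5-sh, however. Between the knockdowns the hypoxia list as a whole did not differ detectably (median 0.02, camera adjusted p = 0.876), though 5 of 23 genes were higher and 6 lower in C-Myc-sh. HIF1A protein was not measured here.

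In the heat shock list of Slc7a5-sh, BAG3, DNAJA1, DNAJB1, DNAJB4 and HSPH1 rose and CACYBP and HSPE1 fell; in C-Myc-sh the list had a median of -0.17 (camera adjusted p = 0.127), with 3 of 14 genes up and 7 down. Between the knockdowns it was lower in C-Myc-sh (median -0.43, camera adjusted p = 0.00304), with 10 of 14 genes lower and 1 higher. In Slc7a5-sh the calls of CACYBP, HSPE1 and HSPH1 were lost without Ctrl-sh replicate 1 (-0.12, -0.16 and 0.22), among other arrays for CACYBP and HSPE1, and HSPH1 turned to -0.28 without the _s_at and _x_at probe sets.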
